A study of Homo sapiens with 6 samples.

How the data were processed

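Bru-seq libraries of primary human dermal fibroblasts were analysed, 2 from each of 3 phases: proliferation, starvation and recovery. All 6 sample titles carry the same cell name. Per the labels' protocols, cells were labelled with 5-bromouridine, total RNA was treated with DNase and fragmented, labelled fragments were precipitated with an anti-BrdU antibody, and libraries were made with a directional kit. Per the submitters' processing notes, reads were aligned with STAR 2.7.9 to the human genome build hg38. The read counter, its strand setting, its treatment of reads with several positions and the annotation release are not given in the sources used here. The authors deposited whole-number counts per gene and, beside them, TPM values. The deposited TPM equals the count divided by the whole length of the gene, introns included, scaled to the same total in each library (largest relative difference 5.2e-15), so short genes weigh more in it than in the counts. Because the strand setting is unknown, reads of overlapping genes cannot be told apart. Of 209 genes the selection rule named, 60 share bases with another tested gene, and genes named in the text whose partner was more abundant are marked there. Near-identical copies, such as histone genes, are uncertain because the treatment of reads with several positions is unknown.

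Each library held between 12464105 and 17116757 counts over 60649 genes, with starvation replicate 1 the deepest. The 2 libraries of each phase differed by more than counting noise (chi-square over degrees of freedom 13.7, 23.1 and 8.73 in proliferation, starvation and recovery), so none was taken for a duplicate of another. Phases come from the labels, and replicates were numbered in accession order, which the labels do not call a pairing. The numbers follow the lower and higher run of library numbers in the sample titles, and the fit without that run as a block gave all values unless the block is named. No column of another sample was used.

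Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3: the filterByExpr filter left 15794 genes, TMM factors scaled the libraries, and the quasi-likelihood F-test compared phases in 1 fit of all 6 libraries with 3 residual degrees of freedom and 5.25 prior degrees of freedom. The common biological coefficient of variation (square root of the common dispersion) was 12.7%. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed, and "rose" and "fell" refer to these. Fold changes are edgeR's. Their standard errors (SE) were derived as the size of the log2 change over the square root of the F statistic. CPM values are TMM-normalised with means and SDs over 2 libraries. Before the data were examined 32 gene lists were fixed, some with shared members, and 28 of them had at least 5 tested members. They were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, with adjustment over all lists and the 3 comparisons, and again with the correlation estimated from the 6 libraries. At the preset value 15, 15 and 17 lists passed in starvation minus proliferation, recovery minus starvation and recovery minus proliferation. With an estimated correlation 0 passed in each, the lowest adjusted p being 0.36. That version rests on the 3 residual degrees of freedom, so few lists could pass it after adjustment. Growth factor receptors in starvation minus proliferation had an estimated correlation of 0.0096, under the preset value, yet the camera p went from 0.043 to 0.14. Failing that version therefore does not by itself show that correlation between genes undoes a result. Other lists had estimated correlations far above the preset 0.01. In starvation minus proliferation these were 0.51 for mitosis, 0.52 for histones, 0.66 for cholesterol and 0.38 for immediate early genes. For such lists the camera p at the preset value may be much too small, and the 2 reasons for failing cannot be told apart. Counts adjusted over the list alone apply the Benjamini-Hochberg step to the members of 1 list.

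Genes were named by a rule fixed at the same time. It took, per comparison, the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those called, with a log2 change of at least 1 in size, a mean of at least 100 counts in the higher phase, and no overlap between the libraries of the compared phases. It added up to 4 members of each list with the smallest adjusted p, and CDKN1A, MKI67, MYC, COL1A1, MMP1 and HMGCS1 in every comparison. Members of lists named beyond these were chosen after their values were seen. Sex-linked marker genes were not reported. Some genes that the rule names are not reported here.

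The procedures were tested on simulated counts for the 15794 genes with 200 genes changed. For starvation minus proliferation edgeR found 19.4% of 1.5-fold, 71.6% of 2-fold and 97% of 4-fold changes, with 10 false calls among 135. For recovery minus starvation it found 10.4%, 76.1% and 97%, with 13 false calls among 135, and with no change simulated between recovery and proliferation it made 1 call. Alternatives were RLE, upper-quartile and library-total scaling, other filters, DESeq2 1.42.0, limma on log2(TPM + 1) and log2(TPM + 0.1), fits of only the compared phases, other thresholds, protein-coding genes only, mitochondrial genes left out, and each library left out in turn. After the data were seen, a block for the runs of library numbers in the sample titles and the removal of a trend with gene length were added.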

Results

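Transcription was measured in primary human dermal fibroblasts, the collagen-producing cells of the skin, in 3 culture phases with 2 libraries each. Proliferating cells were kept in 10% serum. Starved cells were held in low serum for 48 hours, and recovering cells were returned to 10% serum for 24 hours after such a starvation. The sources differ on the low serum: the growth protocol gives 0.1% and the series description 1%. Newly made RNA was labelled with 2 mM 5-bromouridine for 2 hours, at 46 to 48 hours of starvation or 22 to 24 hours of recovery, and recovered with an antibody before sequencing (Bru-seq). The values therefore follow RNA made in that window more than the RNA already present. The libraries held 12464105 to 17116757 counts each. The stated purpose was to find which genes are transcribed in each phase. Of 60649 listed genes, 15794 had enough counts to be tested, and every change below is relative to the other genes of the same library, since no spike-in is named. The labels do not say whether the 2 libraries of a phase came from separate cultures, so p-values measure only the spread between these samples, which may be technical. All 6 sample titles carry the same cell name, so the values speak for those cells and not for fibroblasts of other donors.

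Starved and proliferating cells were compared first. Genes of cell division were lower in starvation: 35 of the 49 tested genes of the mitosis list fell and 0 rose, with a median log2 fold change of -1.41. MKI67, the proliferation marker (chromosome 10, 128096659 to 128126423, hg38), went from 17.0 ± 1.01 to 3.40 ± 0.702 CPM (read counts per unit of TMM-scaled library size, in the usual CPM scale; mean ± SD, n = 2 in each phase), a log2 change of -2.30 ± 0.182 (SE, adjusted p = 0.002, edgeR). ANLN, a scaffold protein of cytokinesis, fell 3.78-fold and the spindle gene ASPM 4.12-fold. Adjusted over the list alone, 42 mitosis genes fell. The list passed the set test (camera, adjusted p = 5.2e-46), but not with an estimated correlation between its genes (adjusted p = 0.36 with an estimated correlation). Of 51 replication-dependent histone genes, 21 fell and 0 rose (31 fell adjusted over the list alone; median -1.04; camera adjusted p = 1.4e-18; adjusted p = 0.41 with an estimated correlation). These genes are near-identical copies, so the count of any 1 of them is uncertain. The DNA replication list moved less, with 5 of 46 members lower, RRM2 and CDC45 among them, and 6 adjusted over the list alone (median -0.21; camera adjusted p = 0.0031, 0.11 without starvation replicate 2; adjusted p = 0.63 with an estimated correlation). Leaving out proliferation replicate 1, proliferation replicate 2 or starvation replicate 1 left 12, 11 and 13 histone genes lower, and 3 DNA replication genes each time.

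Growth arrest genes were higher in starvation. In the list of growth arrest and FOXO targets 10 of 30 rose and 2 fell (11 and 2 adjusted over the list alone; camera adjusted p = 5.5e-07; adjusted p = 0.36 with an estimated correlation). KLF4, a transcription factor, rose 4.06-fold to 62.7 ± 4.18 CPM, and GAS1, a membrane protein first described in arrested fibroblasts, rose 3.58-fold. CDKN1A, the cyclin-dependent kinase inhibitor p21 (chromosome 6, 36676460 to 36687337), rose from 499 ± 35 to 901 ± 38.2 CPM (log2 change 0.85 ± 0.137, adjusted p = 0.012). CDKN1A and BTG2 are in both this list and that of p53 targets, so the results of these lists are not independent. Among p53 targets 8 of 28 rose and 0 fell, BTG2 and BBC3 included (13 rose and 1 fell adjusted over the list alone; camera adjusted p = 9.4e-05; adjusted p = 0.44 with an estimated correlation). Immediate early genes, best known for their burst after serum is added, were also higher: 13 of 30 rose and 0 fell, with a median of 0.84 (20 and 1 adjusted over the list alone; camera adjusted p = 9.4e-13; adjusted p = 0.41 with an estimated correlation). EGR3 rose 8.99-fold and JUND 2.10-fold, while MYC had a log2 change of 0.56 that did not pass the test (adjusted p = 0.10; 0.019 with the lower and higher run of library numbers as a block, a grouping chosen after the data were seen). The p53 count was 5 without proliferation replicate 1, 4 without proliferation replicate 2 (where BBC3 had an adjusted p of 0.076), 4 without starvation replicate 1, and 5 without recovery replicate 1 or 2. In the growth arrest list 0 fell without proliferation replicate 2 or starvation replicate 1, and 8 immediate early genes rose without proliferation replicate 2. SPRY1, an inhibitor of receptor tyrosine kinase signalling (chromosome 4, 123396795 to 123403760), rose from 2.69 ± 0.129 to 22.2 ± 5.22 CPM.

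Among metabolic lists, cholesterol genes rose and amino acid response genes fell in starvation, while fatty acid synthesis did not pass camera. Of 23 genes of cholesterol synthesis and uptake 10 rose and 0 fell, with 17 adjusted over the list alone (median 0.79; camera adjusted p = 4.2e-10; adjusted p = 0.44 with an estimated correlation). The number that rose was 1 without proliferation replicate 2, 1 without starvation replicate 1 and 3 without either recovery library, and it was 3 with a trend in gene length removed, a setting chosen after the data were seen; the median was at least 0.57 in each of these. HMGCS1, an early enzyme of the pathway, rose from 53.3 ± 10.3 to 109 ± 7 CPM (adjusted p = 0.0073). Of 17 fatty acid synthesis genes 2 rose and 0 fell (5 and 3 adjusted over the list alone; median 0.07; camera adjusted p = 0.18, and 0.0022, 0.033 and 0.019 without proliferation replicate 1, without starvation replicate 2 and with the library-number block), and 6 rose without proliferation replicate 1, 4 rose and 2 fell without starvation replicate 2, and 0 rose in the other leave-outs. In the amino acid response list, targets of the transcription factor ATF4, 16 of 33 fell and 0 rose (20 fell and 2 rose adjusted over the list alone; median -0.60; camera adjusted p = 2.2e-10; adjusted p = 0.45 with an estimated correlation). The serine synthesis genes PSAT1 and PHGDH fell 3.86-fold and 2.09-fold, and CHAC1, which degrades glutathione, fell 4.77-fold. The 16 became 2 without proliferation replicate 2, 1 without starvation replicate 1, 7 without recovery replicate 1 and 6 without recovery replicate 2. Leaving out starvation replicate 1 ended the calls of PSAT1 and PHGDH (adjusted p = 0.083 and 0.074), and leaving out proliferation replicate 2 that of PHGDH (0.062). Smaller shifts passed camera for lysosome and autophagy genes (4 of 42 rose, 0 fell; 3 and 0 adjusted over the list alone; adjusted p = 0.58 with an estimated correlation) and for actin cytoskeleton and YAP/SRF targets (1 of 30 rose, 7 fell; 1 and 15 adjusted over the list alone; adjusted p = 0.58 with an estimated correlation), TPM1 and TPM2 among those that fell (adjusted p = 0.16 and 0.084 without proliferation replicate 2, 0.15 and 0.068 without starvation replicate 1). Of the lysosome genes 0 rose without proliferation replicate 2, recovery replicate 1 or recovery replicate 2, 1 without starvation replicate 1, 7 without starvation replicate 2 and 1 with the length trend removed. Of the actin genes 0 fell without proliferation replicate 2, 1 without starvation replicate 1, 14 without starvation replicate 2, 3 without either recovery library and 4 with the length trend removed.

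Matrix genes changed in both directions in starvation. The series title names matrix remodelling in these cells, so the matrix lists are not independent evidence of direction. Of 26 collagen genes 3 rose and 8 fell, with 5 and 9 adjusted over the list alone. COL14A1, a fibril-associated collagen (chromosome 8, 120059780 to 120373573), had the largest rise of any gene named by the selection rule, from 2.68 ± 0.00834 to 53.4 ± 37.6 CPM (log2 change 4.32 ± 0.52, adjusted p = 0.0049), and the 2 starvation libraries stood at 80.0 and 26.8 CPM. COL21A1 and COL5A3 rose as well, with adjusted p values of 0.084 and 0.22 without proliferation replicate 2 and 0.07 and 0.15 without starvation replicate 1, and COL5A3 of 0.055 and 0.058 without proliferation replicate 1 or starvation replicate 2. COL11A1, a fibrillar collagen (chromosome 1, 102876467 to 103108872), went from 16.4 ± 6.32 to 1.32 ± 0.872 CPM (log2 change -3.70 ± 0.433, adjusted p = 0.0047). COL8A1, COL12A1 and COL4A1 fell too, the last of them sharing bases with COL4A2 on the other strand. COL1A1, the main collagen of skin, did not pass the test (2130 ± 171 against 1660 ± 135 CPM, adjusted p = 0.12). The collagen list passed camera in the lower direction (median -0.07, adjusted p = 0.035; adjusted p = 0.61 with an estimated correlation), and without starvation replicate 2 its median was 0.25 with an adjusted p of 0.81, while without recovery replicate 1 or 2 the adjusted p was 0.092 or 0.096. With the length trend removed the collagen list did not pass (median -0.05, camera adjusted p = 0.11). Of 52 matrix glycoproteins and proteoglycans 3 rose and 10 fell (6 and 18 adjusted over the list alone). Their median was 0.01 while their mean was -0.21 and the test pointed lower (adjusted p = 0.019; adjusted p = 0.41 with an estimated correlation). Fibronectin, FN1, fell from 5590 ± 585 to 2000 ± 230 CPM, TGFBI fell 3.40-fold and FBN2 3.91-fold, while PRELP and TNXB rose. TNXB overlaps ATF6B on the same strand. HAPLN1, which links hyaluronan to proteoglycans (chromosome 5, 83637805 to 83720855), had the largest fall, from 39.5 ± 24.0 to 2.00 ± 1.91 CPM (log2 change -4.40 ± 0.626, adjusted p = 0.0079). Matrix proteases and inhibitors did not pass camera (5 of 43 rose and 4 fell, 8 and 8 adjusted over the list alone). CTSK and PLAU rose, and ADAM12 and FAP fell; the calls of PLAU and FAP were lost without proliferation replicate 2 (adjusted p = 0.096 and 0.063) or starvation replicate 1 (0.091 and 0.085), and that of FAP without proliferation replicate 1 (0.063). MMP1, the interstitial collagenase, had a log2 change of 1.07 ± 0.581 and did not pass the test (adjusted p = 0.26; 0.022 with the library-number block). Collagen modification genes did not pass camera either, with 0 of 29 higher and 4 lower (2 higher and 4 lower adjusted over the list alone). PLOD2 and LOXL2 were among the lower, and the LOXL2 call was lost without proliferation replicate 2, at a log2 change of -0.83. With the length trend removed the collagen modification list passed in the lower direction (median -0.13, camera adjusted p = 0.025). TGF-beta targets passed in the lower direction (1 of 35 rose, 6 fell; 2 and 9 adjusted over the list alone; adjusted p = 0.019, 0.085 without starvation replicate 2, where the median was 0.05; adjusted p = 0.43 with an estimated correlation). With proliferation replicate 2 left out, the higher and lower members were 1 and 5 collagens, 2 and 5 glycoproteins and proteoglycans, 1 and 1 proteases and inhibitors, 0 and 1 collagen modification genes, and 0 and 5 TGF-beta targets. With starvation replicate 1 left out they were 1 and 7 collagens and 1 and 2 proteases and inhibitors, and with starvation replicate 2 left out 11 and 6 proteases and inhibitors.

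**Figure D1:**
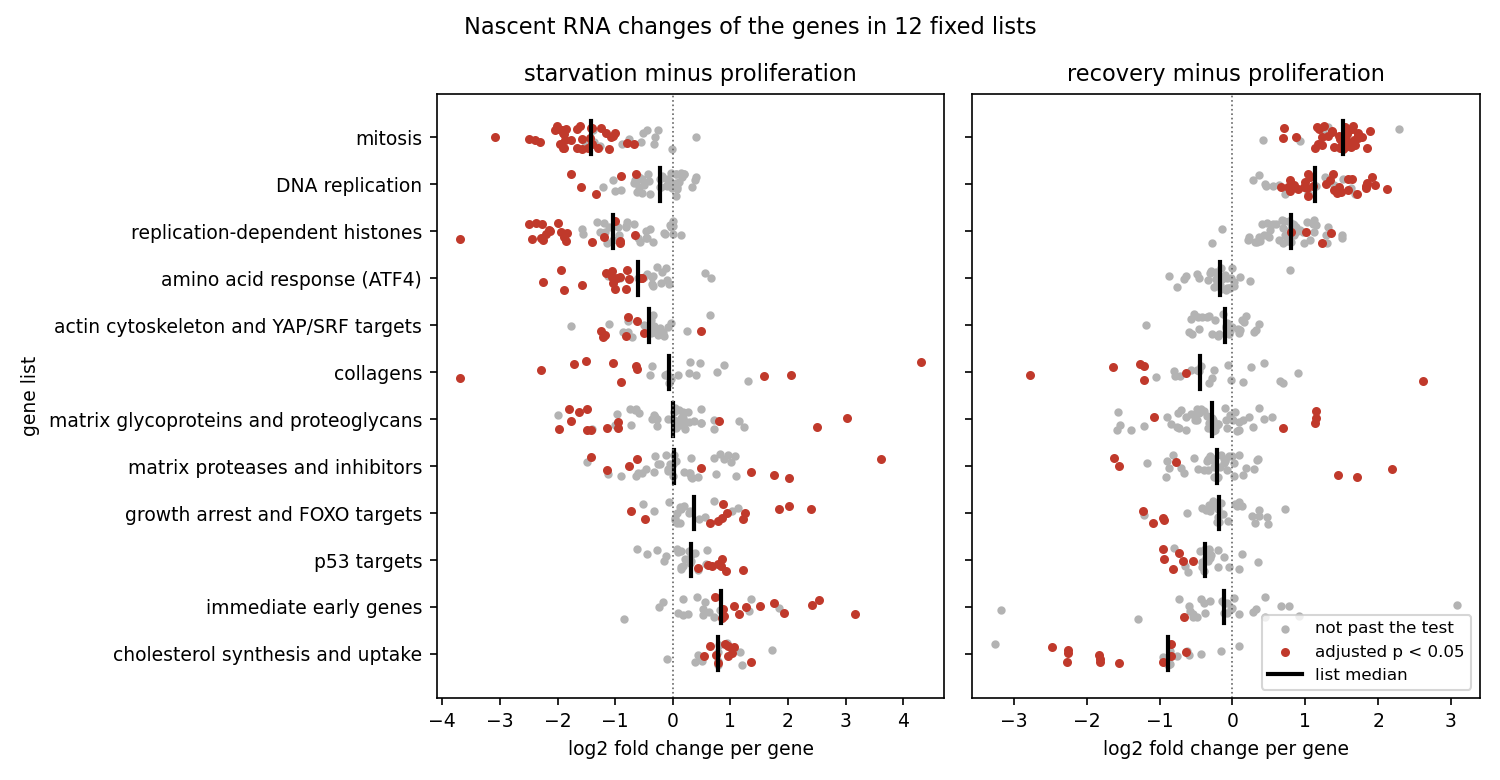
Log2 fold changes of the tested genes in 12 of the gene lists, for starvation minus proliferation (left) and recovery minus proliferation (right). Each point is 1 gene, red where its edgeR adjusted p was under 0.05, and the black bar is the list median. The mitosis median lies at -1.41 on the left and 1.52 on the right.

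In all, 1594 of the 15794 genes changed between starvation and proliferation, 714 higher and 880 lower in starvation, of which 297 and 413 moved at least 2-fold. With scaling by library totals the split was 1957 higher and 605 lower, and with limma on log2(TPM + 1) it was 1135 higher and 259 lower. Other large rises included TENT5C, ADH1B and SLC7A14, and CMKLR1, FABP3, RGS2 and OLFML2A, whose calls were each lost without proliferation replicate 2 (adjusted p = 0.078, 0.084, 0.12 and 0.059). Those of CMKLR1 and FABP3 were also lost without starvation replicate 1 (0.092 and 0.051), and that of RGS2, which overlaps a more abundant long noncoding RNA gene on the other strand, without proliferation replicate 1 (0.067). Other large falls were KCNH1, EDIL3, DIO2, CH25H and ID3, a dominant-negative helix-loop-helix protein. The number of changed genes fell to 347 without proliferation replicate 2, 562 without starvation replicate 1, 804 without recovery replicate 1 and 775 without recovery replicate 2, and rose to 2556 without starvation replicate 2. It was 2687 without a filter on low counts and 671 in a fit of only these phases, and 3348 with the library-number block.

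Recovery was then set against starvation, to show what changed once serum was returned. Cell cycle genes rose almost throughout: 48 of 49 mitosis genes, 40 of 46 DNA replication genes and 40 of 51 replication-dependent histone genes, with 0 lower in each list. Adjusted over the list alone the counts were 48, 43 and 43, and without recovery replicate 2 they were 46, 26 and 25 over all genes tested. The medians were 2.99, 1.38 and 1.82 (camera adjusted p = 8.8e-124, 1.1e-34 and 1.3e-34), and each list had an adjusted p of 0.36 with an estimated correlation. MKI67 reached 40.6 ± 3.33 CPM, 11.8-fold above starvation (adjusted p = 8.2e-05). DLGAP5 rose 23.7-fold, and the kinase TTK, HMMR, KIF18A, CKAP2L and SKA3, which act at the mitotic spindle, were also among the 10 largest rises. DDIAS was another, although it overlaps the more abundant PRCP on the other strand. ID3 (chromosome 1, 23557926 to 23559501) rose most, from 8.5 ± 3.28 to 245 ± 142 CPM (log2 change 4.82 ± 0.451, adjusted p = 0.00051), and its relative ID1 rose 15.7-fold.

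All 23 genes of cholesterol synthesis and uptake fell on recovery, and so did all 23 adjusted over the list alone (median -1.82; camera adjusted p = 4e-32; adjusted p = 0.36 with an estimated correlation). HMGCS1 fell to 29.8 ± 0.678 CPM (adjusted p = 0.00026) and MSMO1 fell 6.64-fold. Fatty acid synthesis followed, with 10 of 17 lower and 0 higher (11 adjusted over the list alone; camera adjusted p = 2.9e-07; adjusted p = 0.43 with an estimated correlation). SCD, the stearoyl-CoA desaturase, went from 343 ± 104 to 23.2 ± 6.59 CPM (adjusted p = 0.0014). Among immediate early genes 1 of 30 rose and 19 fell (1 and 22 adjusted over the list alone; camera adjusted p = 3.7e-11; adjusted p = 0.41 with an estimated correlation). For p53 targets these counts were 1 and 17 of 28 (1 and 20 adjusted over the list alone; camera adjusted p = 1.5e-12; adjusted p = 0.36 with an estimated correlation), and for growth arrest and FOXO targets 0 and 12 of 30 (2 and 17 adjusted over the list alone; camera adjusted p = 6.3e-09; adjusted p = 0.36 with an estimated correlation). CDKN1A fell 3.51-fold and MYC 1.81-fold (adjusted p = 0.017; 0.089, 0.10 and 0.11 without starvation replicate 1, recovery replicate 1 or recovery replicate 2). Of the ATF4 list 12 of 33 rose and 2 fell (17 and 2 adjusted over the list alone; camera adjusted p = 0.00066; adjusted p = 0.63 with an estimated correlation). Cytokines, chemokines and NF-kB targets fell in 10 of 21 cases and rose in 2 (10 and 3 adjusted over the list alone; camera adjusted p = 0.006; adjusted p = 0.45 with an estimated correlation), LIF among those lower. Fewer members passed in some leave-outs. Without recovery replicate 2 these were 5 lower of the fatty acid list, 9 of the immediate early list, 10 of the p53 list and 7 of the growth arrest list, with 0 higher and 0 lower of the ATF4 list and 0 and 3 of the cytokine list. Without recovery replicate 1 the immediate early, p53 and growth arrest lists had 10, 11 and 6 lower, the ATF4 list 7 higher and 0 lower, and the cytokine list 1 and 6. Without starvation replicate 1 the immediate early list had 11 lower, the ATF4 list 2 higher and 0 lower, and the cytokine list 2 and 3.

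The collagen list did not pass camera in this comparison, with 2 of 26 higher and 6 lower (2 and 6 adjusted over the list alone), nor did matrix glycoproteins and proteoglycans, with 13 of 52 higher and 10 lower (13 and 13 adjusted over the list alone). COL14A1 fell 12.3-fold and PRELP 13.1-fold, while TGFBI, FN1 and TNC rose. Matrix proteases and inhibitors did not pass either (camera adjusted p = 0.077; 0.032, 0.033 and 0.0028 without proliferation replicate 1, proliferation replicate 2 or starvation replicate 2, and 0.016 with the library-number block) and split as 6 higher and 12 lower of 43 (7 and 18 adjusted over the list alone), with MMP3 7.10-fold higher and CTSK 3.39-fold lower. The collagen list passed without starvation replicate 2 or recovery replicate 1, in the lower direction (adjusted p = 0.0086 and 0.018). Leaving out starvation replicate 1, recovery replicate 1 or recovery replicate 2 gave 0 and 4, 0 and 6, and 0 and 4 collagens higher and lower, 7 and 9, 8 and 8, and 6 and 4 glycoproteins and proteoglycans, and 4 and 6, 4 and 5, and 3 and 4 proteases and inhibitors. Leaving out starvation replicate 2 gave 3 and 10 collagens and 7 and 21 proteases and inhibitors. COL1A1 and MMP1 did not pass the test (adjusted p = 0.64 and 0.06; 0.59 and 0.0014 with the library-number block). Further large falls were TENT5C and GRIA1, and OLFML2A, CMKLR1, FABP3, ADH1B and C10orf105, whose mean in recovery was under 1 CPM so that their fold is imprecise. C10orf105 lies across CDH23.

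Altogether 3239 genes changed between recovery and starvation, 1648 higher and 1591 lower in recovery. Scaling by library totals gave 1345 higher and 2183 lower, and limma on log2(TPM + 1) gave 724 higher and 2882 lower. The count fell to 1777 without starvation replicate 1, 1398 without recovery replicate 1 and 844 without recovery replicate 2, and was 4867 with the library-number block. All 20 genes named for the largest changes kept their calls in each of the 6 leave-outs.

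**Figure D2:**
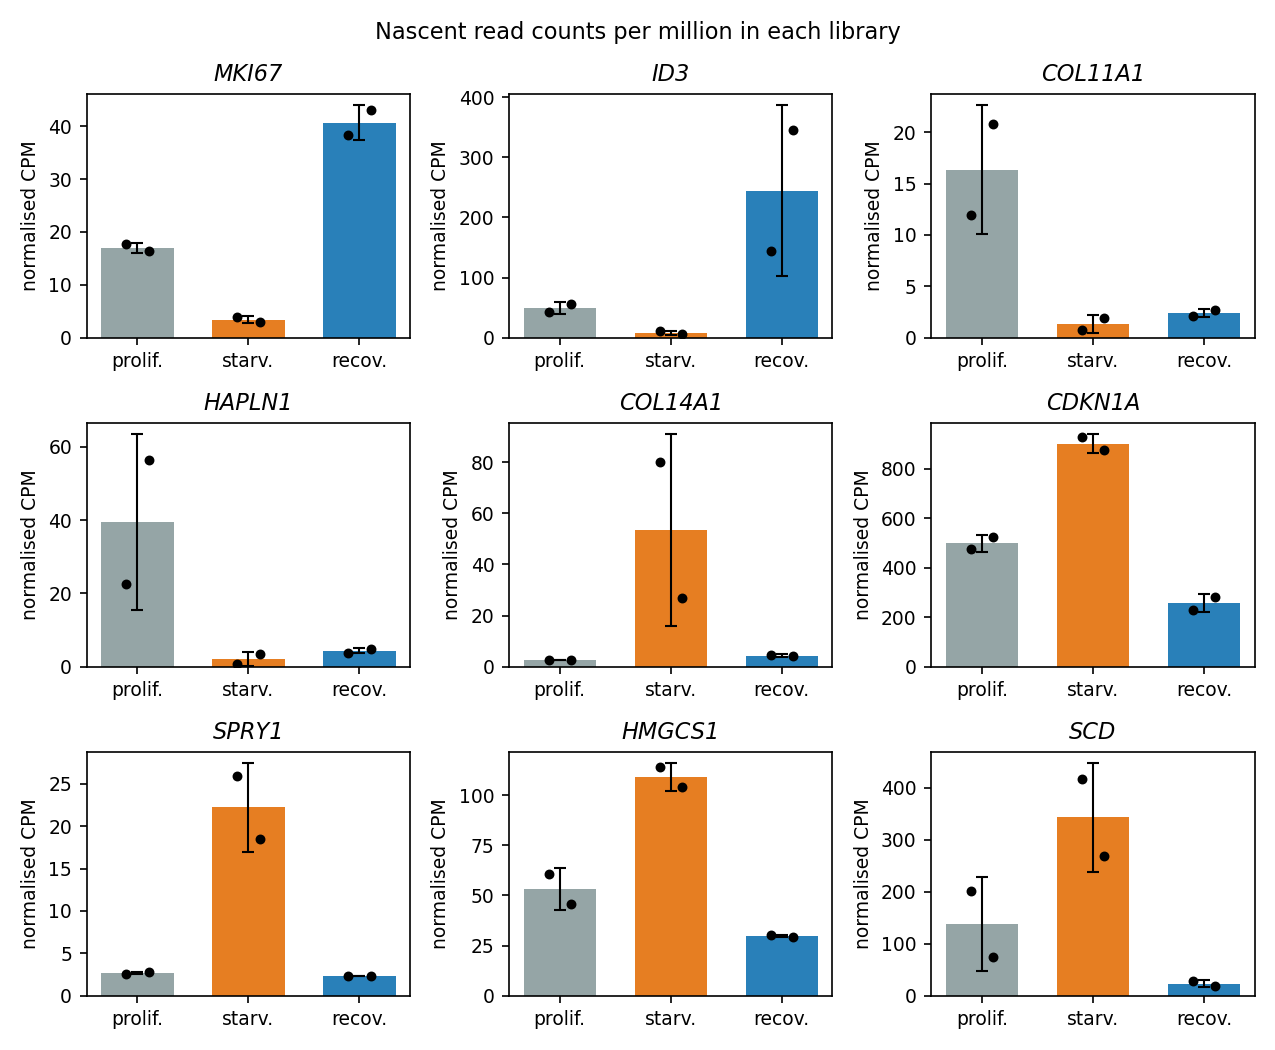
Normalised read counts (CPM) of 9 genes in proliferation, starvation and recovery. Bars are means, points the 2 libraries of each phase, and error bars 1 SD, with each vertical axis starting at 0. CDKN1A stood at 499, 901 and 257 CPM in the 3 phases, and COL11A1 at 16.4, 1.32 and 2.39 CPM.

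Recovered cells were last compared with the proliferating cells. Cell cycle genes stood above their proliferating level: 43 of 49 mitosis genes and 31 of 46 DNA replication genes rose, with 0 lower (48 and 44 adjusted over the list alone). The medians were 1.52 and 1.13 (camera adjusted p = 4.8e-92 and 1.1e-50), and both had an adjusted p of 0.36 with an estimated correlation. MKI67 was 2.39-fold higher (adjusted p = 0.0074), ANLN 2.96-fold and MCM2, part of the replicative helicase, 3.28-fold. Without recovery replicate 2 the log2 changes of MKI67 and MCM2 were 1.17 and 1.62, with adjusted p values of 0.089 and 0.08. The counts of the mitosis and DNA replication lists fell to 6 and 1 without recovery replicate 2, 21 and 5 without proliferation replicate 2, 30 and 11 without proliferation replicate 1, and 33 and 17 without recovery replicate 1, with 0 lower in each and medians of at least 1.34 and 1.02. Of 51 histone genes 4 rose and 0 fell (22 and 0 adjusted over the list alone; median 0.81; camera adjusted p = 1.8e-16; adjusted p = 0.43 with an estimated correlation), and 0 rose without proliferation replicate 1, proliferation replicate 2 or recovery replicate 2, against 13 without either starvation library. Cholesterol genes stood below proliferation, with 12 of 23 lower and 0 higher (19 adjusted over the list alone; median -0.89; camera adjusted p = 3.8e-28; adjusted p = 0.36 with an estimated correlation). DHCR7 and INSIG1 were among the 10 largest falls, at 4.80-fold and 4.79-fold lower (adjusted p = 0.024 and 0.015). Their calls were lost without recovery replicate 2 (adjusted p = 0.20 and 0.16) and without recovery replicate 1 (0.072 and 0.055). The same held for SCD (0.19 and 0.057). Fatty acid synthesis genes fell in 5 of 17 cases and rose in 0 (10 fell adjusted over the list alone; camera adjusted p = 1.1e-10; adjusted p = 0.41 with an estimated correlation). The cholesterol and fatty acid counts were 1 and 0 without recovery replicate 2, 5 and 1 without recovery replicate 1, and 7 and 2 without proliferation replicate 1.

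Some matrix genes differed from the proliferating level in recovery, while the collagen median had been -0.07 in starvation minus proliferation. Of 26 collagens 1 rose and 6 fell (1 and 11 adjusted over the list alone; median -0.45; camera adjusted p = 1.5e-07; adjusted p = 0.37 with an estimated correlation). COL4A1 was 3.11-fold lower and COL11A1 6.83-fold lower, while COL21A1 was 6.14-fold higher; the COL11A1 call was lost without recovery replicate 1 or 2 (adjusted p = 0.057 and 0.099). Matrix glycoproteins and proteoglycans passed camera in the lower direction (median -0.28, adjusted p = 0.0025; adjusted p = 0.36 with an estimated correlation) although 4 of 52 rose, ELN and IGFBP3 among them, and 1 fell (4 and 9 adjusted over the list alone). The ELN and IGFBP3 calls were lost without recovery replicate 2 (adjusted p = 0.29 and 0.27), that of ELN without proliferation replicate 2 (0.15) and that of IGFBP3 without proliferation replicate 1 (0.14). COMP, a cartilage and tendon matrix protein (chromosome 19, 18782773 to 18791305), rose most, from 0.426 ± 0.0109 to 7.82 ± 1.42 CPM (adjusted p = 0.0063). TIMP3, a protease inhibitor, was 4.59-fold higher. CHST8, ID1, GPR137C and ANO3 rose and kept their calls in each of the 6 leave-outs, as did the fall of IL6, from 14 ± 1.56 to 2.35 ± 0.451 CPM (adjusted p = 0.0046); IL6 overlaps the more abundant STEAP1B on the other strand. CDKN1A was lower than in proliferation (257 ± 36.9 CPM, adjusted p = 0.011) and so was HMGCS1 (adjusted p = 0.02). Both calls were lost without recovery replicate 1 (adjusted p = 0.073 and 0.10) or recovery replicate 2 (0.075 and 0.20), that of CDKN1A without proliferation replicate 2 (0.052) and that of HMGCS1 without proliferation replicate 1 (0.078). MYC, COL1A1 and MMP1 did not pass the test (adjusted p = 0.52, 0.11 and 0.64). Of p53 targets 0 of 28 rose and 7 fell (0 and 12 adjusted over the list alone; camera adjusted p = 1.4e-09; adjusted p = 0.37 with an estimated correlation). The 7 became 3 without proliferation replicate 1 and 0 without proliferation replicate 2, recovery replicate 1 or recovery replicate 2. Without recovery replicates 1 and 2 in turn, 3 and 1 collagens fell, and 2 and 0 glycoproteins and proteoglycans rose. These rose in 2 cases without proliferation replicate 1 and 1 without proliferation replicate 2, and fell in 5 and 6 without starvation replicates 1 and 2.

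In this comparison 654 genes changed, 415 higher and 239 lower in recovery. The split was 533 and 183 with library totals, 477 and 416 with DESeq2, and 189 and 58 with limma on log2(TPM + 1). The count rests on few libraries: it was 33 without recovery replicate 2, 301 without recovery replicate 1, 293 without proliferation replicate 1 and 215 without proliferation replicate 2. It was 1445 with the library-number block and 1430 without a filter on low counts. Of the 20 genes with the largest changes 6 kept their calls in each leave-out.

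The 3 comparisons were joined to ask how far starvation changes were undone. Of the 1594 genes changed in starvation, 1190 (74.7%) changed the opposite way on recovery, 560 of the 714 that had risen and 630 of the 880 that had fallen. Independent lists of those sizes would share 71.9 and 91.8 genes. A further view against proliferation found 98 genes still changed the same way, 31 higher and 67 lower (18.8 and 13.3 for independent lists), COL11A1, HAPLN1 and COL4A1 among the lower. The HAPLN1 call against proliferation was lost without proliferation replicate 2, recovery replicate 1 or recovery replicate 2 (adjusted p = 0.067, 0.12 and 0.17), and that of ID3 without proliferation replicate 1, proliferation replicate 2 or recovery replicate 2 (0.079, 0.055 and 0.084). Another 132 had passed proliferation to the other side, 108 of them lower in starvation and higher in recovery (23.1 for independent lists), a set that held MKI67 and ID3, and 24 the reverse (10.8 for independent lists), CDKN1A and HMGCS1 included. The comparisons share libraries, so chance alone links them: across genes, the log2 changes of starvation minus proliferation and recovery minus starvation had a correlation of -0.74 and a covariance of -0.328, against -0.47 and -0.0402 in 20 simulations with no effect. For starvation and recovery, each against proliferation, the correlation was 0.072 and the covariance 0.0215, against 0.53 and 0.0468 simulated, and for recovery against each other phase they were 0.62 and 0.236, against 0.50 and 0.0439. For the pair of starvation and recovery against proliferation both values lay below the simulated ones. The shared libraries were not split so that each comparison used its own library. Part of the larger values in the other pairs, and of the overlaps beyond those of independent lists, may therefore come from the shared libraries. The 1190 genes became 298 without proliferation replicate 2, 428 without starvation replicate 1, 1914 without starvation replicate 2, and 471 and 368 without recovery replicates 1 and 2. As a share of the genes then changed in starvation these were 85.9%, 76.2%, 74.9%, 58.6% and 47.5%. With the library-number block 2443 genes moved back, 315 stayed changed and 334 passed proliferation. For the 98 genes the leave-outs gave 14 to 207, the lowest without recovery replicate 2 and the highest without starvation replicate 2, and for the 132 genes 6 to 171, the lowest without recovery replicate 2.

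Markers of other cell types were read as a check. Of the keratinocyte, melanocyte, immune and adipocyte lists 4, 1, 3 and 3 genes had enough counts to be tested, too few for a set test, and no immune marker passed 8.01 CPM in any library. Single members moved, in both directions: in starvation PPARG was higher (20.3 ± 3.58 to 55.4 ± 12 CPM, adjusted p = 0.0062) and DSP and PTPRC lower than in proliferation (adjusted p = 0.025 and 0.036), and on recovery DSP rose while PPARG, CSF1R and TP63 fell. The calls of DSP and PTPRC in starvation were lost without proliferation replicate 2 (adjusted p = 0.11 and 0.22) or starvation replicate 1 (0.081 and 0.16), that of DSP without proliferation replicate 1 (0.054), and that of PTPRC without recovery replicate 1 or 2 (0.06 and 0.064); PTPRC overlaps a more abundant long noncoding RNA gene on the other strand. Those of DSP, PPARG, CSF1R and TP63 on recovery were lost without recovery replicate 2 (0.17, 0.056, 0.098 and 0.23), those of DSP, CSF1R and TP63 without starvation replicate 1 (0.07, 0.064 and 0.12), and that of TP63 without starvation replicate 2 or recovery replicate 1 (0.052 and 0.072). Endothelial markers did not pass camera in any comparison, although on recovery ERG and EMCN rose and VWF fell among 6 tested (2 and 1 adjusted over the list alone), at means of at most 1.91 CPM in each phase. These 3 calls were lost without starvation replicate 1 (adjusted p = 0.085, 0.097 and 0.18), recovery replicate 1 (0.19, 0.072 and 0.10) or recovery replicate 2 (0.072, 0.23 and 0.20), and those of ERG and EMCN without starvation replicate 2 (0.082 and 0.083). Smooth muscle and pericyte markers passed in recovery against starvation, with 5 of 9 higher, ABCC9 included, and 0 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.0083; adjusted p = 0.36 with an estimated correlation), and 3 higher without starvation replicate 1 and 2 without either recovery library. Mitochondrially encoded genes took 7.58% and 7.76% of the counts in starvation, against 8.33% and 8.73% in proliferation and 8.79% and 9.96% in recovery.

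Changes also followed the length of the gene. In starvation minus proliferation the median log2 change was 0.22 in the shortest of 5 equal groups of the tested genes (up to 9.64 kb) and -0.19 in the longest (over 111 kb), with a Spearman rho of -0.30 across genes, which are not independent replicates. Recovery minus starvation ran the other way, from -0.20 to 0.15 (rho 0.23), and recovery minus proliferation from 0.02 to -0.04 (rho -0.056). Between the 2 libraries of 1 phase rho was 0.12, 0.20 and 0.039 in proliferation, starvation and recovery.

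**Figure D3:**
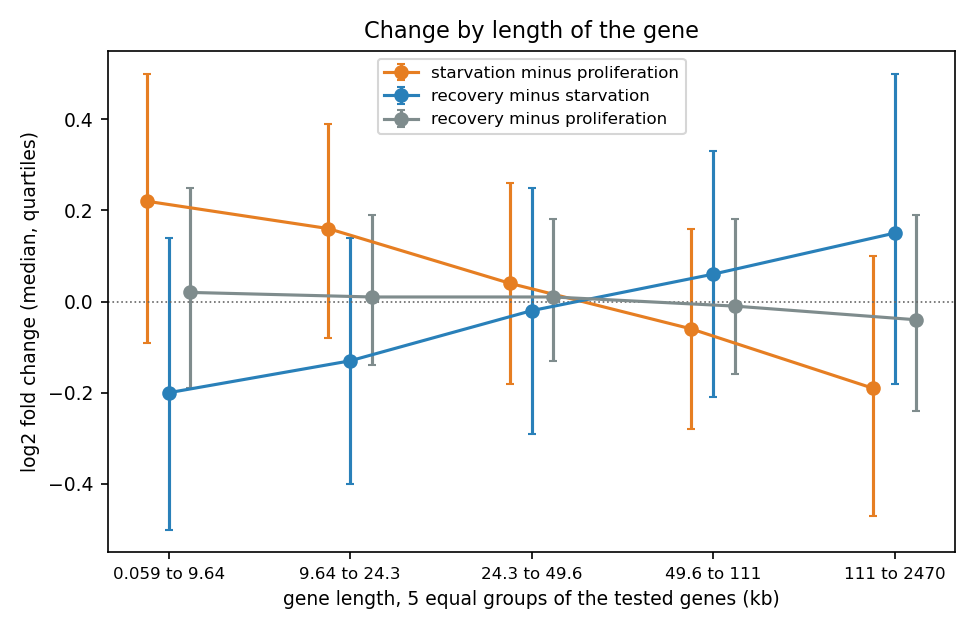
Median log2 fold change, with the lower and upper quartiles as bars, in 5 equal groups of the 15794 tested genes by gene length in kb (horizontal axis), for the 3 comparisons. The starvation minus proliferation line runs from 0.22 to -0.19, and the recovery minus proliferation line from 0.02 to -0.04.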

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

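Tests with the library-number block and with the length trend removed were chosen after the data were seen. The labels give the phases no shared replicate numbers, so the planned fit paired no samples, which does not show that the experiment was unpaired. The sample titles carry library numbers that form a lower and a higher run, with 1 library of each phase in each, and the run was used as a block: deviations correlated by 0.35, 0.15 and 0.15 between phases, and the counts of changed genes rose to 3348 (starvation minus proliferation), 4867 (recovery minus starvation) and 1445 (recovery minus proliferation). Under it 2443 genes moved back on recovery, 315 stayed changed and 334 passed proliferation. Of 313 results for named genes the block ended 0 calls and added 3 (MYC and MMP1 in starvation minus proliferation, MMP1 in recovery minus starvation), and 16, 17 and 17 lists passed the set test, against 15, 15 and 17. List counts and simulated values rest on the fit without it. The labels do not call these runs a batch.

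Scaling, filter and tool moved some counts. With library totals starvation minus proliferation had 2562 changed genes, and all genes' median shifted to 0.216 (-0.126 in recovery minus starvation). Without a filter on low counts the count was 2687, and 1430 for recovery minus proliferation. Fitting only the 2 phases compared gave 671 for starvation minus proliferation, a fit with fewer samples. With limma on log2(TPM + 1) and log2(TPM + 0.1) recovery minus proliferation had 247 and 209 genes, and with DESeq2 165 genes stayed changed after recovery. Library totals leave out the TMM factors, which were 0.956 and 0.924 in proliferation against 1.08 and 1.06 in starvation. That shifts the median of all genes by construction. In the simulation limma on log2(TPM + 1) found 8.96% of 2-fold changes in starvation minus proliferation, against 71.6% for edgeR. Why the counts of the data moved was not tested. Stricter thresholds by construction gave fewer: with a fold of at least 2 as well the counts were 710, 1453 and 419, with 492 moving back, 56 still changed and 80 past proliferation, and at an adjusted p under 0.01 they were 253, 1191 and 122. The other planned settings stayed within 1.5 times.

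Leaving out 1 library at a time, with the lone library of its phase assumed to vary like the others, gave 347 to 2556 genes for starvation minus proliferation, 844 to 3943 for recovery minus starvation and 33 to 971 for recovery minus proliferation. Genes moving back numbered 298 to 1914, those still changed 14 to 207 and those past proliferation 6 to 171. Of 313 results for named genes 155 lost their call in some leave-out and 0 reversed. Lists past the set test numbered 13 to 18, 14 to 18 and 12 to 17, and with an estimated inter-gene correlation 0 in each comparison, against 15, 15 and 17.

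Some lists changed the sign of their median or the direction of their test. The ribosomal protein list in starvation minus proliferation went from 0.16 to -0.02 with the length trend removed (adjusted p = 0.88). In recovery minus proliferation the ATF4 list ranged from -0.41 to 0.09 over the leave-outs (0.09 without proliferation replicate 2, adjusted p = 0.55), and the actin list had a median of 0.03 without that library (adjusted p = 0.85), against -0.11. Over the leave-outs of that comparison the TGF-beta list kept a median below 0, from -0.14 to -0.01. Without recovery replicate 1, however, its test passed upward at a median of -0.05. Its median was 0 with upper-quartile factors and 0.07 with library totals. The cause was not tested. At this depth and with 2 libraries per phase, the simulated recovery of 1.5-fold changes in starvation minus proliferation was 19.4%, so an uncalled gene is not shown to be unchanged. Only 200 genes were changed in the simulation, against 1594 called in the data, so the share found in the data may differ.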

Other observations

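Several fixed lists outside the themes above moved too. Growth factor receptors fell on recovery in 7 of 26 cases and rose in 5 (11 and 5 adjusted over the list alone; camera adjusted p = 0.031, 0.053 without recovery replicate 1; adjusted p = 0.41 with an estimated correlation). Without recovery replicate 2 the receptors fell in 4 cases and rose in 0, without recovery replicate 1 fell in 4, and without starvation replicate 1 rose in 2. KIT, the stem cell factor receptor, rose from 25.9 ± 7.29 to 117 ± 33.2 CPM in starvation (SD, n = 2; edgeR adjusted p = 0.0041) and stood at 22.9 ± 1.61 CPM in recovery. Among circadian clock genes, which did not pass as a list in any comparison, PER2 and PER3 were higher and NPAS2 lower in recovery than in proliferation (log2 changes 0.86, 0.78 and -1.62). These calls were lost without recovery replicate 2 (adjusted p = 0.14, 0.18 and 0.075), those of PER2 and PER3 without proliferation replicate 2 (0.11 and 0.078) or recovery replicate 1 (0.13 and 0.067), and that of PER2 without proliferation replicate 1 (0.055). Interferon-stimulated genes were lower in recovery than in proliferation as a list (median -0.29, camera adjusted p = 0.0029; adjusted p = 0.37 with an estimated correlation), although 0 of 33 members passed the edgeR test (1 higher and 3 lower adjusted over the list alone). Complement genes did not pass as a list, but CLU, or clusterin, rose 4-fold in starvation.

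Mitochondrially encoded genes were lower in starvation as a list (0 of 15 rose, 3 fell; 1 and 8 adjusted over the list alone; camera adjusted p = 0.0067; adjusted p = 0.63 with an estimated correlation) and higher on recovery (5 rose, 0 fell; 7 and 0 adjusted over the list alone; camera adjusted p = 0.0067, 0.059 without recovery replicate 2; adjusted p = 0.63 with an estimated correlation). In starvation 0 of them fell without proliferation replicate 2 and 1 without starvation replicate 1, and on recovery 1 rose without starvation replicate 1 or recovery replicate 2, and 3 without starvation replicate 2 or recovery replicate 1. MT-RNR2 had log2 changes of -0.76 and 0.80, which lost their calls without starvation replicate 1 (edgeR adjusted p = 0.11 and 0.059), the first also without proliferation replicate 2 (0.12) and the second without recovery replicate 2 (0.093). MT-ND6, the gene of the light strand, had 0.58 and -0.02, neither of which passed (edgeR adjusted p = 0.052 and 0.94). Cytosolic ribosomal protein genes had medians of 0.16 and -0.14 in these comparisons and passed camera in both (adjusted p = 0.0083 and 0.027; 0.77 and 0.79 as adjusted p with an estimated correlation), with 1 of 74 higher in the first and 6 lower in the second (1 and 1 adjusted over the list alone). The set calls were lost without starvation replicate 1 (adjusted p = 0.22 and 0.31), the first also without proliferation replicate 2 (0.16) and the second without recovery replicate 2 (0.054), and both with the length trend removed (0.88 and 0.83). The count of 6 became 1 without starvation replicate 1, recovery replicate 1 or recovery replicate 2. Ribosome biogenesis genes did not pass in any. Glycolysis and hypoxia targets did not pass either, though with the length trend removed they passed lower in starvation minus proliferation (camera adjusted p = 0.045). Against proliferation, the ATF4, actin, cytokine, fibroblast marker and smooth muscle lists passed camera in recovery (adjusted p = 0.77, 0.72, 0.58, 0.41 and 0.36 with an estimated correlation), the last higher and the others lower, with at most 3 members of any past the edgeR test (0 and 0, 0 and 0, 2 and 6, 0 and 5, and 2 and 0 higher and lower adjusted over the list alone). The calls of the first 4 were lost in some leave-outs. So were those of growth arrest and FOXO targets, matrix proteases and inhibitors, and collagen modification genes, which were lower as lists in recovery than in proliferation with 4, 3 and 2 members lower and 0, 3 and 0 higher (5, 4 and 4 lower and 1, 3 and 0 higher adjusted over the list alone; adjusted p = 0.41, 0.58 and 0.51 with an estimated correlation). Lysosome and autophagy genes fell on recovery in 9 of 42 cases and rose in 0 (9 and 0 adjusted over the list alone; camera adjusted p = 0.0078; adjusted p = 0.61 with an estimated correlation), and in 3, 0 and 1 cases without starvation replicate 1, recovery replicate 1 and recovery replicate 2. Gene families by symbol stem were tested after the data were seen: 17 of 642 tests over 214 families passed camera, FGF genes lower and AKR genes higher in starvation among them, and with an estimated correlation the adjusted p of these was 1.

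The tests of the patterns below were written before their results were seen, but on patterns found in these data, except that the exonic-share test was added only after the ribosomal protein test had left its question open, and the comparison of mitosis genes with length-matched genes was chosen after the other results were seen. Short genes were higher and long genes lower in starvation (rho -0.30). The tables argue against the deepest library or the expression level as the whole cause: rho was -0.22 without starvation replicate 1 and averaged -0.24 within 5 groups of mean expression. From the lowest to the highest of these groups rho was -0.096, -0.17, -0.32, -0.3 and -0.29, so the trend was weaker among genes of low expression. The trend had the same sign in the lower and higher run of library numbers (rho -0.29 and -0.25, and 0.25 and 0.17 for recovery minus starvation), but variation between libraries stays open, since the 2 starvation libraries alone gave a rho of 0.20 in size. Carry-over of unlabelled mature RNA cannot be told apart from these values: ribosomal protein genes lay -0.047 from length-matched genes, within the spread of draws, and rho with exonic share averaged 0.016 within 5 groups of gene length. A slower or shorter passage of polymerase through long genes in starvation is a hypothesis that gene-level counts cannot test.

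Immediate early genes were higher in starvation, when no serum had been added (median 0.84). They are short, but with the length trend removed the median was 0.64, and the lowest median over the 4 leave-outs of a proliferation or starvation library was 0.61. A single library does not account for the whole shift in these tests. The trend with length was smaller than the shift, with a median of 0.22 in the shortest group of genes. The outcome with the trend removed was therefore foreseeable and adds no separate evidence. A response to handling or to the labelling medium, applied alike to each phase by the protocol, was not tested. Transcription induced by starvation itself may be behind it, which remains a hypothesis.

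Cell cycle genes were above proliferation in recovery (mitosis median 1.52). The tables argue against a single library, with a median of at least 1.34 over the 4 leave-outs of a proliferation or recovery library. Genes of the same lengths had a median of 0.0077, so length alone did not raise such genes. That value was foreseeable, since this comparison had little trend with length (rho -0.056), and it adds no separate evidence. The medians of at least 1.51 under 3 other scalings and of 1.48 with the length trend removed decide nothing, because these settings moved all genes' median by at most 0.084 and any gene by at most 0.11, and the effect of scaling stays open without a spike-in. Cells re-entering the cycle together at 22 to 24 hours, or a proliferating culture that was denser and so cycled less, could each give such values. The labels give no cell density or phase fractions, and these were not told apart.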
